A study of Macaca mulatta with 12 samples.

How the data were processed

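Nuclei were isolated from frozen amygdala tissue of rhesus macaques and profiled by single-nucleus RNA sequencing. Per the labels' protocols, libraries were made with the 10x Genomics Chromium Single Cell 3′ kit of version 2, with about 15000 nuclei loaded per channel for an expected 9000 per sample, and sequenced as 150 bp paired-end reads. The deposited barcodes begin like those of the version 3 kit, so the kit version is not settled. Only the 3′ end of each transcript is read in this assay, UMIs remove copies made by PCR, and nuclear RNA is rich in unspliced transcripts, so levels are those of nuclear RNA. The 12 labelled samples form 1 group, and their titles carry specimen numbers up to 3 with library numbers up to 4 under each.

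The deposited values are raw UMI counts per gene and nucleus: all were whole numbers, from 0 to 705, in 19708 gene rows and 26400 nuclei. The authors' processing used fastp and Cell Ranger 3.0.0, per the submitters' processing notes, which also name the genome build GRCh38. As 5142 rows carry macaque Ensembl identifiers, the build and annotation behind the counts are not settled, and no coordinates are given here. A reference table gave symbols to 797 of those rows. Rows named as mitochondrial numbered 0, so no filter on mitochondrial counts could be applied. Detected genes per nucleus ran from 390 to 4999, with none at 5000 or above. Each barcode ends in 1 of 3 suffixes, and no label or header says which sample, specimen or channel a suffix stands for. The nuclei were therefore treated as 1 pool, as had been fixed for that case, and the planned tests between classes over specimens, with edgeR and camera, could not be run. No p-value, standard error or standard deviation over samples is given. The 3 barcode sets are used only to see whether a direction recurs, since they may be technical.

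Gene lists, marker genes, clustering settings, the fold threshold and most other settings to be tried were fixed before the data were examined. Genes were parted before clustering: markers went to the clustering part (9747 genes), genes of the lists to the held-out part (9961 genes), and other genes by a hash of their name. Differences between classes and between neuronal sub-clusters are reported for held-out genes only. Among the genes named for small clusters and for regions at the end, EBF3, RELN, BHLHE22, CALB1 and RSPO2 were open to the clustering, as were the markers GAD1 and GAD2. Of 90 marker genes 80 were present, and of 312 list genes 285. Nuclei with at least 200 detected genes were kept, which left out 0. The highest Scrublet doublet scores within each barcode set were left out as presumed doublets at 0.8% per 1000 nuclei, which removed 677, 634 and 551 nuclei (7.36, 7.12 and 6.64%) and left 24538. Counts were scaled to 10000 per nucleus and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 gave 22 clusters, without batch correction (scanpy 1.11.5, igraph 0.11.9, scikit-learn 1.9.0, Python 3.11.15). Neuronal classes were clustered again in the same way.

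Clusters were named from the fixed markers, with thresholds set after the data were seen. Inhibitory neurons needed GAD1 and GAD2 to sum to over 300 CPM. Excitatory neurons needed SLC17A7 over 75 CPM, SV2B over 45 and RBFOX3 over 600. Other classes needed a mean log2 marker ratio over 3, against all other nuclei and with 5 CPM added to each side, and a lead of at least 1 over the next class. An unnamed cluster of at least 200 nuclei was clustered again. Clusters with a median doublet score over 0.06 stayed unnamed, a rule also added after the data were seen. That rule alone kept 3 clusters with 290 nuclei out of a class (1.18% of nuclei; 1.63, 1.05 and 0.826% in the 3 barcode sets). By their markers alone 197 of these nuclei would have been named oligodendrocytes, 58 microglia and 35 inhibitory neurons. The naming rule had no branch for immature neurons, so no cluster could be given that name. Their marker score was taken for first-level clusters only and reached at most 1.01, in an unnamed cluster of 803 nuclei. The sub-clusters of that cluster were not scored for it, so the presence of immature neurons was not tested.

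For each class, counts were summed over nuclei and scaled to CPM, and each sum has an exact 95% Poisson interval. Shares have exact Clopper-Pearson intervals. Excitatory were compared with inhibitory neurons, oligodendrocytes with their precursors, and astrocytes, microglia and endothelial cells each with the mean CPM of the other 9 classes. A gene was measured if either side held at least 50 UMIs and each side would have held at least 10 at the higher of both levels. The latter condition was added after the data were seen. A log2 fold is the log2 of the ratio of the CPM values, with a count of 0 set to a floor of 3 counts. A list is described by its members at least 2-fold higher or lower and by the percentile of its median among 10000 random lists of the same size, drawn from the 100 genes nearest in level to each member. Percentiles are given for lists with at least 5 measured genes. The lists for myelin, astrocyte transport, innate immunity and the blood-brain barrier hold genes known from oligodendrocytes, astrocytes, microglia and endothelial cells. Those classes were named from other genes known from them, so a high median of that list checks the name and is no independent finding.

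The rule for named genes took, from each list assigned to a comparison, up to 2 genes in each direction, and over all held-out genes with a symbol and a mean log2 CPM of at least 5, up to 5 in each direction. In neuronal sub-clusters it took up to 2 list genes each. A false discovery rate had been part of the rule. As no test was possible, it was replaced by at least 50 UMIs, a 2-fold difference and the same sign in all 3 barcode sets. Other members past 2-fold are named with their list. Sub-clusters with fewer than 20 nuclei in any barcode set were not described.

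The calculation was tested on simulated counts with 200 genes changed. Each other gene had 1 pooled level in all classes, and counts were drawn with Poisson error only at the real depths of the classes. For excitatory against inhibitory neurons, 98.0 to 100% of genes set at a log2 fold of 1.5 or 3 in either direction passed the 2-fold threshold, against 0.08% of 7417 unchanged genes. For oligodendrocytes against precursors it was 96.0 to 100%, against 0.06% of 1765. For endothelial cells against the mean of the other classes it was 98.0 to 100%, against 2.59% of 2315. The Poisson interval held the true level in 95.6, 96.9 and 98.1% of genes in these 3 comparisons, which follows from the Poisson draw. The simulation held no spread between nuclei, no free RNA and no differences among the other classes. Its rates therefore check the calculation and are not error rates of the real comparisons.

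Precision follows depth. The classes ranged from 114 endothelial to 11024 excitatory nuclei, with medians from 1108 to 7968 UMIs, so low genes are measured far better in neurons than in vascular cells or microglia. Alternatives kept the presumed doublets, required at least 500 detected genes, thinned each nucleus to 1000 UMIs, set the resolution to 1.0 or clustered on all genes. Alternatives added after the data were seen left out barcode set 1, 2 or 3, the excitatory cluster highest in PROX1, the one highest in ST18, or the rule on doublet scores.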

Results

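Gene expression was measured in single nuclei isolated from frozen amygdala tissue of rhesus macaques (Macaca mulatta). The amygdala is a group of nuclei in the temporal lobe that takes part in fear, reward and social behaviour, and the study set out to sort its cells into molecular types. All 12 labelled samples belonged to 1 group, so the comparisons the design implies are between cell classes, not between treatments. The deposited counts covered 19708 genes in 26400 nuclei, with 151526883 unique molecular identifiers (UMIs, 1 per captured transcript) in all. Nuclei carried 3 barcode suffixes, called barcode sets here, with 9201, 8900 and 8299 nuclei and 52231758, 51570932 and 47724193 UMIs. The median nucleus had 5053.5 UMIs and 2452 detected genes, and the set medians lay between 5009 and 5116 UMIs. No label tied a barcode set to an animal or a sample, so the pool counted as 1 sample. There is therefore no replicate error and no test behind any difference given here. Intervals are exact 95% intervals that cover counting error only, and each value called higher or lower had the same direction in all 3 barcode sets unless stated.

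Neurons made up 61.6% of the 24538 nuclei kept, and excitatory neurons outnumbered inhibitory neurons by 2.70 to 1. Both values depend on the cluster highest in PROX1, which held 5085 of the 11024 excitatory nuclei (46.1%). Whether that cluster comes from the amygdala is not settled. Excitatory neurons, which release glutamate, were 44.9% of nuclei (44.3 to 45.6%). Inhibitory neurons, which release GABA, were 16.7% (16.2 to 17.1%). Astrocytes, the glia that clear transmitter and feed neurons, were 24.5% (24.0 to 25.04%). Ependymal cells, the ciliated lining of the ventricles, were 3.23% (3.01 to 3.46%). The oligodendrocyte lineage was small, with 1.83% myelinating oligodendrocytes (1.66 to 2.00%), 1.52% precursors (1.37 to 1.68%) and 0.387% committed precursors on the way to myelination (0.313 to 0.473%). Microglia, the resident macrophages of the brain, were 0.738% (0.634 to 0.853%). Vessels gave 0.672% mural cells (0.574 to 0.783%) and 0.465% endothelial cells (0.383 to 0.558%). A further 5.08% stayed unnamed (4.81 to 5.36%). Each name stands for a cluster that resembles that cell type by marker genes fixed in advance, so "microglia" means microglia-like.

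The shares of the 3 largest classes differed little between barcode sets. Excitatory neurons ranged from 44.7 to 45.1%, inhibitory neurons from 16.5 to 16.9% and astrocytes from 24.3 to 24.8%, and the ratio of excitatory to inhibitory nuclei was 2.66, 2.69 and 2.74. Mural cells ranged from 0.555 to 0.883% and oligodendrocytes from 1.502 to 2.21%. The latter spread depends on a rule on doublet scores, added after the data were seen, that kept 197 nuclei with oligodendrocyte markers and 58 with microglial markers unnamed. Named by their markers, they bring oligodendrocytes to 2.63% (2.69, 2.48 and 2.72% in the 3 barcode sets) and microglia to 0.974%. Depth differed strongly between classes. The median was 7968 UMIs in excitatory neurons, 5620 in inhibitory neurons, 1733 in astrocytes, 1704 in oligodendrocytes and 1108 in microglia. An upper limit near 5000 detected genes, inferred from the counts, lay closest to the excitatory neurons, so their share is the share among the nuclei deposited.

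**Figure D1:**
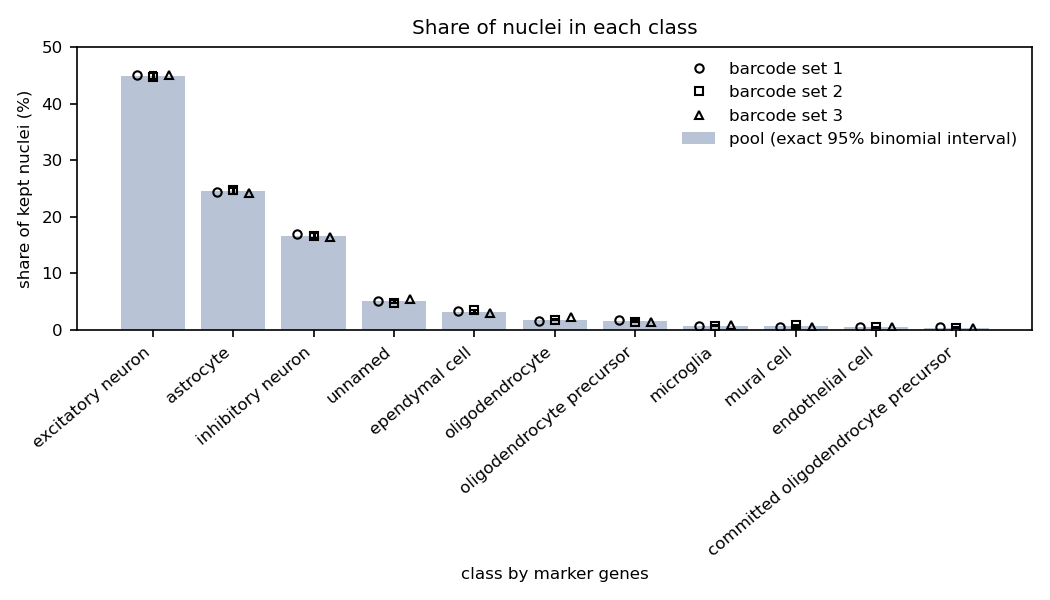
Bars give the share of the 24538 kept nuclei in each class (y axis, percent, starting at 0) with its exact 95% binomial interval, and open symbols give the share in each of the 3 barcode sets. Excitatory neurons (44.9%), astrocytes (24.5%) and inhibitory neurons (16.7%) lead, and the symbols of the sets lie close together in those classes.

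Neuronal transcripts were also present in the glial and vascular nuclei. RBFOX3, which encodes the neuronal nuclear protein NeuN, stood at 836 CPM (counts scaled to the total of the class) in excitatory neurons, 495 in inhibitory neurons, 52.0 in astrocytes, 42.4 in oligodendrocytes and 84.8 in microglia. SYT1, a synaptic vesicle gene, stood at 3238 CPM in excitatory neurons and at 867, 1343, 1232 and 756 CPM in astrocytes, oligodendrocytes, microglia and endothelial cells. SLC17A7, a marker used to name excitatory neurons together with RBFOX3 and SV2B, stood at 134 CPM in them, 25.3 in inhibitory neurons, 71.7 in astrocytes, 93.7 in microglia, 88.2 in mural cells and 76.1 in endothelial cells. A UMI of RBFOX3 was seen in 98.2% of excitatory neurons (median 7968 UMIs) and in 7.55% of astrocytes (median 1733 UMIs).

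Excitatory and inhibitory neurons differed most in their peptide genes, in several receptor subunits and in some immediate early genes. Neuropeptide genes were lower in excitatory neurons: 14 of the 20 measured were at least 2-fold lower, 1 was at least 2-fold higher, and the median log2 fold was −2.28, below each of 10000 random lists matched on level. NXPH1, which encodes the secreted neurexin ligand neurexophilin, stood at 16.6 CPM (15.8 to 17.4) in excitatory and 1896 (1879 to 1914) in inhibitory neurons. PNOC, the precursor of nociceptin, was lower by a log2 fold of −3.91. SST, NPY, VIP, CCK, CRH, TAC1, TAC3, PENK, PTHLH, NXPH2, SCG2 and VGF were the other members that were lower. PDYN, which encodes prodynorphin, was the 1 peptide gene that was higher in excitatory neurons (log2 1.48).

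Of the 24 glutamate receptor genes, 10 were at least 2-fold lower and 3 at least 2-fold higher in excitatory neurons. GRIA4, an AMPA receptor subunit, stood at 39.9 CPM (38.7 to 41.2) against 1377 (1363 to 1392) in inhibitory neurons, a log2 fold of −5.11. GRM8, a presynaptic metabotropic receptor, was lower by −3.33. GRIK1, GRIK2, GRIK3, GRIN2C, GRIN2D, GRIN3A and GRM4 were among the others that were lower. GRM2, another metabotropic receptor, was higher (8.02 against 0.853 CPM, log2 3.23), as were GRIK4 (log2 1.35) and GRIK5 (log2 1.04). The median of the list was 0.20, at the 89.9th percentile of matched random lists, with members on both sides.

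Of the 13 GABA receptor genes measured, GABRA5 (152 against 29.6 CPM, log2 2.36) and GABRA2 (1.37) were among the 3 that were at least 2-fold higher in excitatory neurons. GABRB2 (−1.44) was among the 2 that were lower, and the list's median was −0.59, at the 0.16th percentile. Among 18 monoamine and acetylcholine receptor genes, 7 were lower and 1 was higher, with a median of −0.58 at the 0.04th percentile. HTR3A, an ion channel gated by serotonin, was lower by −5.90, and the muscarinic receptor gene CHRM2 stood at 6.04 CPM (5.55 to 6.56) against 204 (198.6 to 210). HTR2C, HTR1F, ADRA1A, CHRNA7 and HRH1 were lower too. CHRM4, another muscarinic receptor, was higher (log2 2.11) on 132 and 8 UMIs.

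Peptide and hormone receptor genes divided. Of 21 measured, 7 were higher in excitatory neurons (CRHR1, CRHR2, AVPR1A, NPY1R, SSTR2, CCKBR and VIPR1) and 5 were lower (CNR1, OPRK1, HCRTR2, VIPR2 and NTSR2), with a median of 0.18 at the 98.0th percentile, which was −0.31 without the excitatory cluster highest in PROX1. VIPR1, a receptor of vasoactive intestinal peptide, had 665 UMIs in excitatory and 6 in inhibitory neurons (log2 4.86, interval 3.73 to 6.31, and 3.27 after thinning each nucleus to 1000 UMIs). AVPR1A, a vasopressin receptor, had 111 and 1 (log2 4.86, interval 2.35 to 10.17). CNR1, the main cannabinoid receptor of the brain, stood at 73.3 CPM (71.6 to 75.02) against 742 (732 to 753) in inhibitory neurons, and OPRK1, the kappa opioid receptor, was lower by −3.08. Of 14 genes of steroid receptors and the stress response, 3 were higher and 3 were lower, with a median of −0.31 at the 7.43rd percentile. FKBP5, which dampens glucocorticoid receptor activity, was higher (83.1 against 14.5 CPM, log2 2.52), as were the progesterone receptor gene PGR (1.89, and 0.00 without that cluster) and the mineralocorticoid receptor gene NR3C2 (1.80). CRHBP, which encodes a protein that binds corticotropin-releasing hormone, was lower (−3.63), as was the thyroid hormone receptor gene THRB (−2.03).

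Of 18 immediate early genes, which neuronal activity can induce within minutes to hours, 9 were measured. Of these, 6 were at least 2-fold higher in excitatory neurons and none was as much lower. Their median was 1.57, at the 99.99th percentile. Neuronal activity itself was not measured. FOS (−0.47), EGR1 (−0.59) and NR4A1 (0.20) lay within 2-fold. BDNF, a neurotrophin, stood at 90.6 CPM (88.7 to 92.6) against 8.41 (7.31 to 9.64). NR4A2 was higher by 2.84, NR4A3 by 2.06, ARC by 1.95, FOSL2 by 1.57 and HOMER1 by 1.06. Of 32 voltage-gated channel genes, 23 lay within 2-fold, 5 were higher and 4 were lower, with a median of 0.13 at the 93.0th percentile. The T-type calcium channel genes CACNA1H (log2 4.54) and CACNA1I (2.23) were higher in excitatory neurons. KCNC2, a potassium channel of fast-spiking interneurons, was lower (278 against 2550 CPM, log2 −3.20), as was the sodium channel gene SCN9A (−2.67). Over all genes kept out of clustering and past the level minimum, the 5 largest ratios in favour of excitatory neurons were those of KIAA1211L (4.99), TSPAN18 (4.12), NTNG2 (3.87), RASAL1 (3.83) and PTK2B (3.69). The 5 largest in favour of inhibitory neurons were those of NXPH1 (−6.84), PDE3A (−5.96), NHS (−5.79), BMP6 (−5.72) and BTBD11 (−5.61).

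Over the 8 lists, 29 list genes were at least 2-fold higher and 45 at least 2-fold lower in excitatory neurons. Without the excitatory cluster highest in PROX1, which held 5085 of the 11024 excitatory nuclei, the median of glutamate receptors was −0.03, that of peptide and hormone receptors −0.31, and the log2 fold of PGR was 0.00, that of GRM2 2.20 and that of BTBD11 −6.61. Leaving out barcode set 1, 2 or 3 gave 4.24, 4.26 and 2.73 for AVPR1A. Thinned to 1000 UMIs, the log2 folds of named genes that moved over 1.5 times besides that of VIPR1 were those of GRM2 (5.18), HTR3A (−7.91), PDYN (2.09), PNOC (−4.60), PGR (2.49) and CRHBP (−2.83). With presumed doublets kept they were those of NXPH1 (−5.80), PDE3A (−5.15), BMP6 (−5.06) and AVPR1A (3.01). Another excitatory cluster of 590 nuclei was high in ST18 (1094 CPM) and in ERG (136 CPM), markers fixed for oligodendrocytes and endothelial cells, yet had MBP at 52.1 CPM and FLT1 at 3.83 CPM beside RBFOX3 at 857 CPM.

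**Figure D2:**
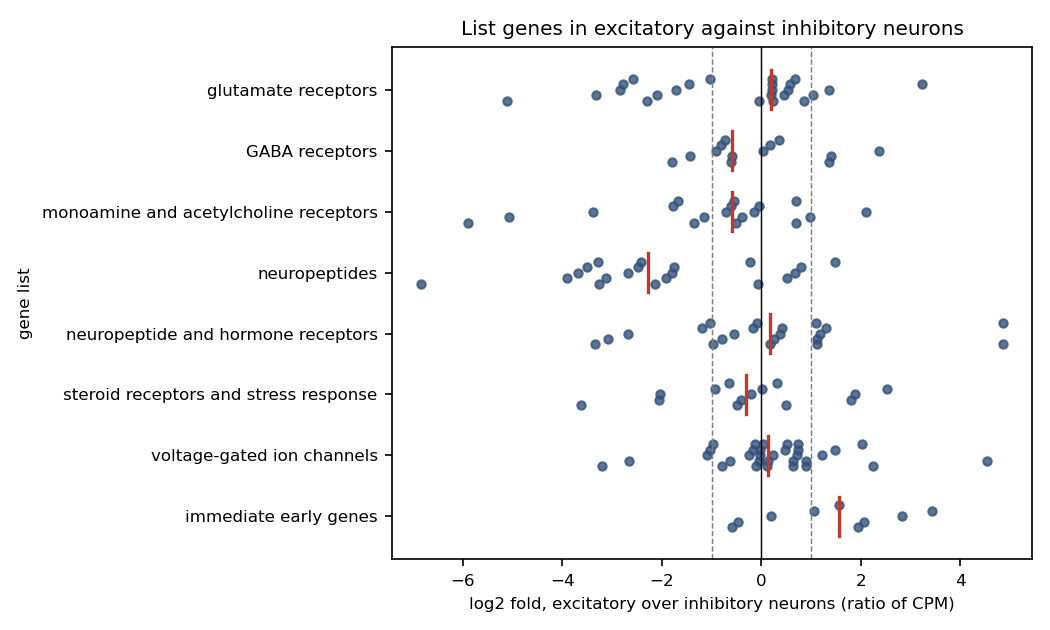
Each point is 1 measured gene of a fixed list (y axis) at its log2 fold of CPM in excitatory over inhibitory neurons (x axis), red bars are list medians and dashed lines mark 2-fold. Neuropeptides lie to the left (median −2.28) and immediate early genes to the right (median 1.57), while glutamate receptors spread over both sides (median 0.20).

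Within the inhibitory neurons, 12 sub-clusters could be described, and 77 list genes were at least 2-fold above the mean of the other sub-clusters in at least 1 of them. Peptide genes were unevenly spread. CRH, the stress peptide corticotropin-releasing hormone, stood at 158 CPM (141 to 177) in sub-cluster I1, 9.64-fold above the mean of the others, together with VIP at 45.7 CPM (36.6 to 56.4). VIP was also high in I7 at 44.7 CPM (36.4 to 54.3), next to CNR1 at 3147 CPM, 7.002-fold above the others. SST, somatostatin, reached 307 CPM (273 to 346) in I12, where CRHBP reached 105 CPM (85.1 to 128). NPY stood at 63.5 CPM in I12 and 56.7 CPM in I6. PENK, the enkephalin precursor, reached 44.2 CPM (35.1 to 54.9) in I5, beside GRM8 at 1571 CPM. TAC1, the substance P precursor, stood at 89.7 CPM in I12, 59.4 CPM in I6 and 88.2 CPM in I9, the last beside CHRM2 at 618 CPM.

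The remaining inhibitory sub-clusters were led among list genes by receptors, channels and a proteoglycan. HTR3A reached 104 CPM (92.8 to 116) in I4, 7.94-fold above the others, together with the proteoglycan gene GPC5 at 5609 CPM. The dopamine receptor gene DRD3 led I3 (33.1 CPM, 8.11-fold) and I8 (26.5 CPM, 5.65-fold), with ADRA1A at 586 CPM in the former and TACR1 at 234 CPM in the latter. GRIN3A, an NMDA receptor subunit, stood at 1208 CPM in I2 beside NR4A3 at 40.8 CPM. GRIN2C (35.3 CPM) and the extrasynaptic GABA receptor subunit gene GABRD (91.4 CPM) led I10. HCRTR2, an orexin receptor, led I11 at 220 CPM (189 to 254), 7.70-fold above the others, beside KCND2 at 1947 CPM. A 13th sub-cluster had 14 nuclei in barcode set 2, under the minimum of 20, and was not described.

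**Figure D3:**
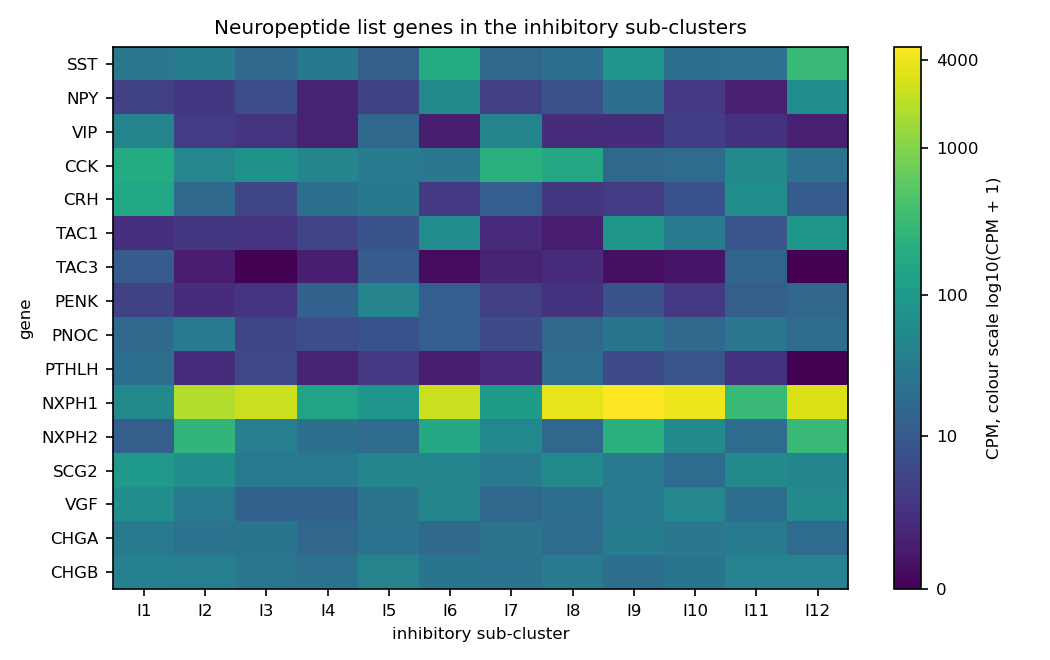
Colour gives the level in CPM (log scale, colour bar) of 16 neuropeptide list genes (y axis) in the 12 described inhibitory sub-clusters (x axis). CRH is brightest in I1 (158 CPM), SST in I12 (307 CPM) and VIP in I1 and I7 (45.7 and 44.7 CPM), and NXPH1 ranges from 54.7 to 4899 CPM.

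Within the excitatory neurons, 13 sub-clusters were described, and 93 list genes were at least 2-fold above the mean of the others in at least 1. HTR1F, a serotonin receptor, stood at 1373 CPM (1280 to 1471) in the 72 nuclei of E13 against a mean of 13.0 in the others, a 106-fold difference, and KCNH5 was 21.8-fold higher there. CHRM2 was 44.5-fold higher in the 108 nuclei of E12 (175 CPM, 150 to 203), as was NXPH1 by 20.4-fold. CARTPT, which encodes the CART peptide, was 19.8-fold higher in E10 (43.9 CPM), with UGT8 at 72.8 CPM. OPRM1, the mu opioid receptor, was 18.6-fold higher in E8 (330 CPM, 315 to 345), and DRD3 was 10.2-fold higher there. NTS, neurotensin, was 11.3-fold higher in E11 (45.3 CPM), beside GPC5 at 2755 CPM.

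The ratios of the genes named in the other excitatory sub-clusters were smaller. The nuclei of E1, E3 and E4 came mainly from the cluster highest in PROX1, whose origin is not settled. Each of these sub-clusters was set against a mean that included the others. PGR was 5.50-fold higher in the 2490 nuclei of E1 (14.3 CPM, 12.5 to 16.2) and the substance P receptor gene TACR1 was 5.30-fold higher (142 CPM). FA2H was 6.03-fold and the muscarinic receptor gene CHRM3 3.54-fold higher in E2. ABCA1 was 6.77-fold higher in E3, and the neuropeptide Y receptor gene NPY1R was 4.96-fold higher in E3 and 3.29-fold higher in E4. DRD2 was 6.64-fold higher in E4 and 4.79-fold higher in E7, where HTR2C was 4.57-fold higher. TSC22D3 was 2.43-fold higher in E6. The potassium channel gene KCNQ5 was 2.68-fold higher in E5, next to ACSS1 at 3.75-fold, and 2.73-fold higher in E9, next to ABCC4 at 3.56-fold.

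Oligodendrocytes differed from their precursors by the whole measured myelin list, while how far ion channels and receptors were lower depended on which nuclei were counted. Of 18 myelin and paranode genes 12 were measured, and all 12 were at least 2-fold higher in oligodendrocytes. The median log2 fold was 4.45, above each of 10000 matched random lists. OPALIN, a protein of the myelin sheath, stood at 719 CPM (661 to 780) against 8.16 (3.28 to 16.8) in precursors. TMEM144 had 123 and 2 UMIs (log2 6.04, interval 4.15 to 9.10, 4.69 without barcode set 1 and 5.39 when clustered on all genes). The others were ANLN, CLDN11, SEPTIN4, MYRF, TF, MAL, CNTN2, FA2H, UGT8 and NFASC. ANLN (log2 5.84, and 6.85 at Leiden resolution 1.0), which encodes anillin, was also the only gene of the cell cycle list that could be measured, so proliferation was not assessable here. Among 7 cholesterol genes, FDFT1 (1.32) and SQLE (1.22) of the synthesis pathway were among those higher and the exporter gene ABCA1 was lower (−1.56). The median of that list was 0.96 at the 97.7th percentile, and 0.17 without barcode set 3.

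Of 21 voltage-gated channel genes, 17 were at least 2-fold lower in oligodendrocytes than in precursors and none higher, with a median of −1.77, below each matched random list. KCND2 stood at 263 CPM (229 to 301) against 3021 (2905 to 3139), and KCNH5 was lower by −3.67. Of 18 glutamate receptor genes, 10 were lower and 1 higher, with a median of −1.12 at the 0.19th percentile. GRIN2D was lower by −3.06. GRM3, a metabotropic receptor gene, went the other way, at 775 CPM (715 to 838) against 59.5 (44.3 to 78.2). Of 7 GABA receptor genes, 4 were lower, GABRA3 by −3.56 and GABRG3 by −2.13 among them, with a median of −1.24 at the 3.19th percentile and −0.64 without barcode set 2.

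The size of these differences depends on the rule on doublet scores. With the 197 nuclei it kept out counted as oligodendrocytes (median 5916 UMIs, against 1704 in those named), 15 list genes were lower in place of 32. The median was 3.32 for myelin genes, −0.73 for channels, −0.60 for glutamate receptors, 0.72 for cholesterol genes and 0.19 for GABA receptors, the last with its sign changed. KCND2 was then −1.96, KCNH5 −1.95, GRIN2D −1.52, GABRA3 −1.998, GABRG3 −0.81 and ABCA1 −0.08, while OPALIN was 5.51 (from 6.46), TMEM144 5.01 and ANLN 4.78. The median doublet score of these nuclei was 0.084, against 0.004 in the named oligodendrocytes. Whether they are doublets with neurons or oligodendrocytes was not tested.

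Over held-out genes past the level minimum, RNF220 stood at 4799 CPM (4648 to 4953) in oligodendrocytes and 49.0 (35.3 to 66.2) in precursors, and HHIP, an inhibitor of hedgehog signalling, was higher by 6.24. DTHD1 had 93 and 1 UMIs (log2 6.64, interval 4.12 to 11.95), and PPP1R14A had 65 and 1 (log2 6.12, interval 3.59 to 11.44). In the other direction, STK32A had no UMI in oligodendrocytes and 334 in precursors, lower by an exact interval that ends at log2 −6.40. SUSD5 had 1 and 129 UMIs (log2 −6.92, interval −12.23 to −4.41). FSTL4 (−5.39) and CABLES1 (−5.34) were lower, as was NXPH1 (67.3 against 2328 CPM). In all, 16 list genes were higher and 32 lower. Without barcode set 3 the log2 folds of DTHD1, SUSD5 and FSTL4 were 4.61, −4.54 and −4.67. Without sets 1 and 2 in turn that of DTHD1 was 5.998 and 5.96. Thinned to 1000 UMIs, DTHD1, HHIP, SUSD5, FSTL4 and CABLES1 stood at 5.46, 5.50, −4.38, −4.45 and −4.56. With fewer nuclei or UMIs a count of 0 for STK32A bounds its difference less tightly. Without the rule on doublet scores STK32A was −2.69, SUSD5 −3.41, FSTL4 −3.01, CABLES1 −1.58 and NXPH1 −3.22, and RNF220, HHIP, DTHD1 and PPP1R14A were 5.67, 5.32, 5.67 and 5.20.

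**Figure D4:**
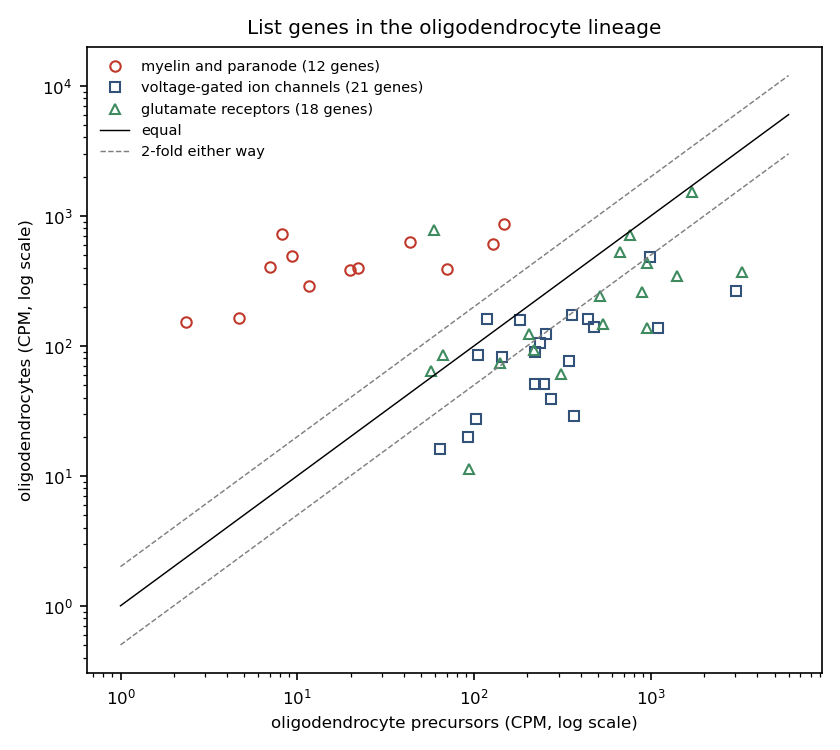
Each symbol is 1 measured gene at its CPM in oligodendrocyte precursors (x axis, log scale) and in oligodendrocytes (y axis, log scale), with a solid line at equality and dashed lines at 2-fold. All 12 myelin genes lie above the upper dashed line, and 17 of 21 channel genes and 10 of 18 glutamate receptor genes lie below the lower one.

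Astrocytes were set beside the mean of the other 9 classes, each class counting equally. Of 17 genes of astrocyte transport and metabolism, 15 were at least 2-fold higher, with a median log2 fold of 2.23, above each matched random list. SLC7A10, a serine and glycine transporter, was higher by 5.95, and SLC25A18, a mitochondrial glutamate carrier, stood at 421 CPM (409 to 433) against 26.6. GLUL, which makes glutamine from glutamate, was higher by 2.68, and KCNJ10, a potassium channel, by 2.26. Of 19 cholesterol genes, 4 were higher and 1 lower, with a median of 0.61 at the 99.99th percentile. APOE, which carries cholesterol between cells, stood at 1085 CPM (1065 to 1104) against 381, and HMGCS1, an enzyme of cholesterol synthesis, was higher by 1.28, while the exporter gene ABCG1 was lower by −3.22. The highest other class came close for APOE (1080 CPM in microglia) and HMGCS1 (30.5 CPM in committed oligodendrocyte precursors, against 32.6 in astrocytes).

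Receptor genes past 2-fold in astrocytes were more often lower than higher. Of 24 glutamate receptor genes, 8 were lower and 2 higher, with a median of −0.92, below each matched random list. GRM8 (−3.20) and GRIK3 (−3.04) were among the lower ones. GRIN2C (log2 3.56) was higher, and 4.22 without barcode set 3, and GRM3 stood at 1151 CPM (1131 to 1172) against 398. Mural cells had more GRM3, at 1994 CPM. Among 17 monoamine and acetylcholine receptor genes, 8 were lower, HTR1F by −5.47 and HTR3A by −2.18 among them, with a median of −0.92 at the 0.10th percentile. DRD1 was higher (log2 1.34), at a low level of 4.48 CPM in astrocytes. The means of the other classes for HTR1F and GRM8, 273 and 362 CPM, were set largely by mural cells, which had 2044 and 1881. Of 14 steroid and stress genes, PER1, a clock gene that glucocorticoids induce, was higher by 2.05 and 5 were lower, with a median of −0.49 at the 5.22nd percentile. PER1 stood at 21.8 CPM in astrocytes and 21.1 in endothelial cells. TSC22D3 was lower by −2.45 and PGR by −2.38, the latter on 11 UMIs in astrocytes, −1.68 without barcode set 2 and −3.11 when thinned to 1000 UMIs, where PER1 was 1.45. The mean of the other classes for PGR, 5.33 CPM, rests largely on endothelial cells (29.6 CPM on 7 UMIs).

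Over held-out genes past the level minimum, the largest ratios in favour of astrocytes were those of ACSBG1 (5.49), RGS20 (5.36), ALDH1A1 (5.32), ETNPPL (4.83) and SLC25A18 (3.98). The largest against them were those of genes high in vascular or ependymal classes, MECOM (−8.13), ITGA1 (−6.78), TNFSF10 (−6.54), FLI1 (−6.47) and TTC34 (−5.97). Their order is not firm, as TNFSF10 was −7.29 without barcode set 1, ITGA1 −7.75 when thinned to 1000 UMIs, and MECOM and TTC34 −7.40 and −5.24 with presumed doublets kept. SLC7A10 was 6.72 when thinned. Without the rule on doublet scores SLC7A10 was 3.79, ACSBG1 3.87, RGS20 3.59, ALDH1A1 3.65, ETNPPL 3.28 and SLC25A18 3.06. In all, 23 list genes were higher and 22 lower. Neuronal RBFOX3 stood at 52.0 CPM and SYT1 at 867 CPM in the same nuclei.

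Immune genes were high in microglia, which follows in part from naming the class by markers of such cells. Of the 22 genes of complement, antigen presentation and innate immunity, 12 were measured. All 12 were at least 2-fold higher than in the mean of the other classes. The median log2 fold was 6.55, above each matched random list. A list gene low in the other classes was measured only if it was high in microglia. ITGAM, a complement receptor, stood at 357 CPM (283 to 444) against 2.82, and MRC1, a mannose receptor, at 317 (247 to 400) against 2.52. C1QB, C1QC and C3 of the complement system, TREM2, CD14, SYK, LYN, IRF8, SPI1 and RUNX1 were higher too. Among 12 cholesterol genes APOE (log2 1.502, 1080 CPM) and LPL (80.3 CPM against 28.5, on 18 UMIs) were higher, with a median of 0.35 at the 76.4th percentile. Among 6 steroid and stress genes FKBP5 was higher (2.17), SGK1 (−1.62) and THRB (−1.02) were lower and the median was 0.00, at the 43.8th percentile. OPRM1 stood at 236 CPM (177 to 309) on 53 UMIs against 25.1, the 1 of 3 measured peptide receptor genes past 2-fold.

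Over held-out genes past the level minimum, F13A1 (7.40), IKZF1 (7.09) and FGD2 (7.001) were higher in microglia, and EPAS1, SMOC1, ACACB, DOCK6 and CLIC4 had 1 UMI each. The fixed markers held no class for other macrophages, so any such nuclei would not be told apart from microglia here. In all, 16 list genes were higher and 3 lower in the 181 microglia, whose nuclei also held RBFOX3 at 84.8 CPM. After thinning each nucleus to 1000 UMIs, which 63 microglia did not reach, 9 were higher and 1 lower and the immune median was 4.50. Without barcode set 1 the log2 folds of MRC1 and F13A1 were 6.36 and 6.81, and without set 3 the count of lower list genes was 1 and the immune median 5.96. Clustered on all genes, FGD2 was 6.16. The 58 nuclei that the rule on doublet scores kept out had a median score of 0.079 and 2873 UMIs, against 0.023 and 1108 in the named microglia. Whether they are doublets was not tested. Without that rule, 7 list genes were lower, the immune median was 5.61, the steroid and stress median −0.80 and OPRM1 2.61. F13A1 was then 6.76, IKZF1 6.40, FGD2 6.16 and ITGAM 6.36 (from 6.98), while EPAS1, SMOC1, ACACB, DOCK6 and CLIC4 were −3.66, −4.37, −0.20, −3.90 and −2.26.

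Endothelial cells, with 114 nuclei, were marked by carriers of the blood-brain barrier. Of 13 barrier transport genes 9 were measured, and 8 of these were at least 2-fold higher than in the mean of the other classes. The median log2 fold was 4.15, above each matched random list. ABCG2, a drug efflux pump, stood at 1137 CPM (1005 to 1281) against 21.0, and SLC38A5, a glutamine transporter, at 211 (157 to 279) against 2.21. The glucose transporter gene SLC2A1 (5.49), SLCO1A2 (5.64), SLC16A1 (4.15), the transferrin receptor gene TFRC (3.91), SLC39A10 (2.49) and SLCO2B1 (1.92) were the others. Not all were particular to endothelial cells. In the pool SLCO2B1 was also at least 2-fold higher in microglia than in the mean of their other classes, and SLCO1A2 in oligodendrocytes than in precursors. Of 8 steroid and stress genes, 3 were higher and 1 lower, with a median of 0.87 at the 97.4th percentile. The glucocorticoid receptor gene NR3C1 stood at 647 CPM (548 to 758) against 209, and TSC22D3 (2.51), a glucocorticoid-induced gene, and ESR2 (1.40, on 18 UMIs and lower in barcode set 2) were higher, while SGK1 was lower (−1.53). Of 4 immune genes, SYK (−1.60, on 4 UMIs), RUNX1 and ITGAM were lower in the pool, against a mean that includes microglia (335 CPM of SYK). RUNX1 and ITGAM had no UMI in endothelial cells, were set at the floor of 3 counts and did not keep their direction in every barcode set.

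Over held-out genes past the level minimum, the transcription factor gene MECOM stood at 5333 CPM (5043 to 5636) in endothelial cells against 7.01. EMCN was higher by 6.84, VEGFC by 6.71 and EGFL7 by 6.25, and TNFSF10 had 91 UMIs in endothelial cells and 13 in all other classes. BMPER, SMOC1, CABLES1, DNAH2 and DCDC1 had 1 UMI each in endothelial cells. In all, 11 list genes were higher and 4 lower. The count of lower genes was 2 after thinning to 1000 UMIs and between 1 and 2 without any 1 barcode set, where the immune median was between 0.12 and 0.64 in place of −1.67, and VEGFC was 6.06 without set 1. EGFL7 was 7.78 when thinned, and SLC38A5 was 7.42 when clustered on all genes. Without the rule on doublet scores the count of lower genes was 1 and the immune median 0.49.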

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

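Both results in this part lie in small clusters that the comparisons left out, were picked after the data were seen, and were set against the level that a count of 0 allows; no technical or biological explanation was tested.

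An unnamed cluster of 30 nuclei carried 84 UMIs of TP73, a transcription factor gene of the p53 family that was not used for clustering. That is 537 CPM, against a floor of 19.2 CPM (3 counts over the cluster) and 7.85 CPM in all other nuclei, and 26 of the 30 nuclei had a UMI. The same nuclei held EBF3 at 754 CPM against 0.870, NDNF at 678 CPM against 6.64 and RELN, which encodes the secreted protein reelin, at 21604 CPM against 275; EBF3 and RELN were open to the clustering. Genes of inhibitory neurons were near the floor, with 3 UMIs of GAD1 and 2 of GAD2. These are genes known from Cajal-Retzius neurons of the developing cortex. NHLH2 and CALB2, also on the list of such genes but not looked at when the cluster was noticed, stood at 102 CPM on 16 UMIs and 32.0 CPM on 5 UMIs, and LHX5, LHX1 and EOMES are not in the table by name. The nuclei were uneven over the barcode sets, with 21, 5 and 4.

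Another unnamed cluster, of 35 nuclei (16, 11 and 8 per barcode set), carried 387 UMIs of HTR2C, a serotonin receptor gene of the monoamine receptor list. That is 1563 CPM, against a floor of 12.1 CPM and 43.3 CPM in all other nuclei, and 34 of the 35 nuclei had a UMI. HTR3A stood at 291 CPM against 4.70, GAD2 at 557 CPM against 83.5 and SLC18A2, the vesicular monoamine transporter gene, at 279 CPM against 6.999 in the other nuclei. MEIS2 stood at 569 CPM. The cluster's median doublet score of 0.071 lay above the limit of 0.06, which kept it unnamed.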

How the results depend on the processing

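Leaving out a barcode set, the excitatory cluster highest in PROX1 or that highest in ST18, or the rule on doublet scores, was chosen after the data were seen; the other settings were fixed before. No paired analysis was possible because the table ties no nucleus to a specimen or library. For the same reason DESeq2, testing without a filter on low counts, without the replicate block, on sums per library, without each specimen, with an estimated correlation or with fry were not run.

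Over all comparisons and settings, 94 counts of list genes stayed within 1.5 times of the reported count and 11 did not. Of the list medians, 177 stayed within 0.1 log2 units, 72 moved further and 11 changed sign. Of the log2 folds of genes named by the rule and reported here, 589 stayed within 0.1 and 445 moved further without a change of sign, and 58 named genes moved over 1.5 times under at least 1 setting. Of the class shares, 67 stayed within their binomial interval and 13 did not. Some genes fell below the measured minimum under an alternative and have no value there. Counts and medians of the excitatory and astrocyte comparisons stayed close without the cluster highest in ST18.

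With presumed doublets kept, excitatory neurons were 46.2% and astrocytes 23.1%. With at least 500 detected genes, the share of committed oligodendrocyte precursors was 0.298%, mural cells 0.501%, and 1 list gene was lower in microglia. At Leiden resolution 1.0, excitatory neurons were 42.3%, astrocytes 22.2% and committed oligodendrocyte precursors 0.310%. Clustered on all genes, astrocytes were 23.6% and committed oligodendrocyte precursors 0.306%. Thinned to 1000 UMIs, 9 list genes were higher and 1 lower in microglia and 2 lower in endothelial cells. Mural cells were 0.565% without barcode set 2 and oligodendrocytes 1.65% without barcode set 3. The cause was not tested.

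Without barcode set 1, 2 list genes were lower in endothelial cells. Without barcode set 2 it was 1, and without barcode set 3 it was 1 in endothelial cells and 1 in microglia. The median of peptide and hormone receptors in microglia, −0.63 over 3 genes, was 1.34 when thinned, 0.99 without barcode set 1 and 1.28 without set 3. The median of immune genes in endothelial cells, −1.67 over 4 genes of which 2 had no UMI, was 0.56 when thinned and 0.12, 0.64 and 0.52 without barcode set 1, 2 and 3. The floor that replaces a count of 0 is higher in smaller pools, and fewer genes are measured, so both medians rest on too few genes to carry a direction. Without the cluster highest in PROX1, the excitatory against inhibitory medians were −0.03 for glutamate receptors and −0.31 for peptide and hormone receptors, and the cause was not tested.

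Without the rule on doublet scores, which was itself added after the data were seen, oligodendrocytes were 2.63% and microglia 0.974%. The list genes lower in oligodendrocytes than in precursors then numbered 15, those lower in microglia 7 and those lower in endothelial cells 1, the median of GABA receptors in oligodendrocytes was 0.19 in place of −1.24, and that of immune genes in endothelial cells was 0.49. The 197 nuclei added to oligodendrocytes had a median of 5916 UMIs and a median doublet score of 0.084, against 1704 and 0.004. The cause was not tested.

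Depth limits most what can be said of microglia and vascular cells: 63 of 181 microglia, 26 of 165 mural cells and 13 of 114 endothelial cells had fewer than 1000 UMIs, against 0 of 11024 excitatory neurons.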

Other observations

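The tests of free RNA, of the barcode sets and of the limit on detected genes in this part were chosen after the result was seen, and the genes named in the next paragraphs were picked after their values were seen. Mural cells, the contractile and pericyte cells of vessel walls, had 6 of 129 measured list genes at least 2-fold above the mean of the other classes. HTR1F, a serotonin receptor gene, stood at 2044 CPM (1867 to 2234) in mural cells, 43.9-fold above that mean, and the next class, endothelial cells, had 296 CPM. Metabotropic glutamate receptor genes were high as well, GRM8 at 1881 CPM (1711 to 2063) and GRM3 at 1994 CPM (1819 to 2182), above inhibitory neurons (437 CPM of GRM8) and astrocytes (1151 CPM of GRM3). CACNA1C and ABCA1 were 3.82-fold and 2.43-fold higher.

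Ependymal cells had 8 of 220 measured list genes at least 2-fold higher. The potassium channel gene KCNN3 stood at 255 CPM (230 to 281), the adrenergic receptor gene ADRA1A at 255 CPM (231 to 282), the heat shock gene HSPH1, of the list for dissociation stress, at 145 CPM (126 to 165) against a mean of 46.2, the cystine transporter gene SLC7A11 at 164 CPM and the estrogen receptor gene ESR1 at 66.5 CPM (54.3 to 80.7). Committed oligodendrocyte precursors had 13 of 130. MYRF, a transcription factor gene of myelination, stood at 531 CPM (446 to 627) there against 288 in oligodendrocytes, and NFASC, a paranode gene, at 1520 CPM (1374 to 1676) against 604. FA2H (538 against 862 CPM) and CLDN11 (313 against 492 CPM) were below oligodendrocytes, while the potassium channel gene KCNB2 reached 1436 CPM against 658 in excitatory neurons, the next class.

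The largest excitatory cluster, with 46.1% of excitatory nuclei, was the one highest in PROX1 (264 CPM against a mean of 3.41 in the other excitatory clusters), a gene of the dentate granule neurons of the hippocampus, which adjoins the amygdala. Free RNA in the droplets, which would reach all clusters, was set against 10 dentate genes. Of these, 6 lay at least 4-fold above the other excitatory clusters beyond counting error. All 4 genes that drew attention are among the 6, so the bound of at least 3 was met in advance and the count decides nothing. The other 2, BHLHE22 and CALB1, were open to the clustering. The cluster was picked as the highest in PROX1, so the excess of that gene is no independent test. MALRD1 (216 against 12.7 CPM) and TLL1 (263 against 25.7 CPM) also drew attention. All 3 were kept out of the clustering, and differences of this size between excitatory clusters argue against evenly shared free RNA as the whole cause. None marks this cluster alone, as inhibitory sub-clusters averaged 69.8 CPM of PROX1, 83.8 of TLL1 and 10.5 of MALRD1. Earlier forms of this test gave a median of 1.21 log2 units (10 genes against astrocytes, undecided) and of 3.72 (the 4 genes that drew attention). This form was chosen after both. Nuclei of the whole amygdala, central and intercalated cells included, stay open: no inhibitory sub-cluster had more than 1 of 9 genes of those cells at least 4-fold higher, under the bound of 2 set before, but that bound was wrong, as it says nothing of an excitatory cluster and the unnamed cluster with MEIS2 at 569 CPM was outside the test. Nuclei of hippocampal tissue in the pool may be a source but cannot be told apart from other sources, as 2 of 6 dentate genes not seen before were at least 4-fold higher (BHLHE22 and CALB1, both open to the clustering), between the bounds of at least 3 and at most 1. Of the other dentate genes not seen before, TDO2 had 0 UMIs in that cluster and DSP 26. C1QL2 (24.8 against 19.1 CPM) and NPNT (7.01 against 27.7 CPM) were not 4-fold higher there. A neuron of the amygdala itself that uses PROX1 stays open as untested.

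Levels in the 3 barcode sets were close but not the same: over 9958 genes with at least 1000 UMIs, the median fold between the highest and lowest set was 1.05. One nuclear suspension loaded in 3 channels could give this and so could 3 animals dissected separately, and the 2 cannot be told apart. That 0% of those genes differed 1.5-fold restates the pattern, and though separate animals had been predicted to give at least 1%, that bound and the largest fold, 1.42, cannot be judged because no spread between known animals is in these data. The sets still differed by more than any of 100 random splits of the nuclei in the classes tested. The mean chi-square per degree of freedom between sets was 1.2358 in the cluster highest in PROX1, against at most 1.1854 in the splits. It was 1.1996 against at most 1.1367 in astrocytes, and 1.6033 against at most 1.4585 in inhibitory neurons. No spread between channels of 1 suspension is known here, so this does not decide between the 2 sources. The Y-linked gene UTY stood at 218.6, 218.8 and 218.2 CPM, which animals of 1 sex would also allow. The histocompatibility gene MAMU-A stood at 40.1, 36.1 and 40.5 CPM. No biological explanation was tested.

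The deepest nuclei stopped at 1 number of detected genes: 150 nuclei had at least 4800 genes and 0 had 5000 or more, consistent with an upper limit applied before deposit. Excitatory neurons made up 90.7% of the 389 kept nuclei with at least 4500 genes, 2.02 times their share of all kept nuclei, so the limit may have taken mostly excitatory neurons. How many nuclei it took cannot be read from the counts. No biological explanation was tested.

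Among genes on lists for parts of the amygdala and hippocampus, picked after their values were seen, FOXP2 (inhibitory neurons of the central and intercalated amygdala) stood at 571 CPM and FNDC1 (hippocampal CA1 and subiculum) at 67.4 CPM in the excitatory cluster of 108 nuclei. RSPO2 (basolateral and medial amygdala) stood at 48.0 CPM in another of 262 nuclei. LMO3 of the same list was highest in the cluster of 108 nuclei (366 CPM), while SIM1 and OTP had 1 UMI each in their highest cluster. AMIGO2 (5.76 CPM) and RGS14 (78.0 CPM), of the list for hippocampal CA3, CA2 and mossy neurons, were highest in an excitatory cluster of 533 nuclei. CALB2 of that list was highest in another of 332 nuclei (5.49 CPM). Where these clusters come from was not tested. The cluster of 108 nuclei was excitatory by its markers, so FOXP2 alone does not tie it to those inhibitory neurons.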
